A study of Arabidopsis thaliana with 6 samples.

How the data were processed

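RNA was measured in seedlings of Arabidopsis thaliana that had been kept in darkness for 3 days and then moved to light for 1 day. For all 6 samples the labels also give 3 days of stratification and a 2 h light pulse of 100 µmol photons per square metre and second. The 6 libraries came from 3 wild-type (Col-0) and 3 bbx14-1 samples, grouped by the genotype in the labels. Per the labels' protocols, ribosomal RNA was removed from total RNA and strand-specific (dUTP) libraries were made from random-primed cDNA, so that transcripts without a poly(A) tail, including those of plastids and mitochondria, could be counted. Nothing in the labels says that the samples of a group came from separately grown batches, so p-values measure the spread between these samples, which may be partly technical.

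The deposited values are normalized read counts per gene, which the authors divided by a size factor for each library, per the file name. The submitters' processing notes name Trimmomatic, FastQC, TopHat2 2.1.1, featureCounts and DESeq2, with the genome build TAIR10. The strand setting of the counting, the annotation release and the handling of reads with several matches are not given in the sources used here. The table holds 36917 genes and writes decimals with a comma. Every value above 0 was a whole multiple of the smallest value of its library within a tolerance of 0.01, so reads per gene were recovered for 100% of values. Recovered totals ran from 20939505 to 32621183 reads per library. A floor of 3 reads corresponds to 2.40 to 3.77 normalized counts, depending on the library, and covers counting error only. No pair of libraries within a group agreed within sampling noise: the chi-square statistic per degree of freedom was 7.78 at its lowest, so no library was treated as a copy of another. That comparison with counting noise does not tell separate samples from separate preparations of the same RNA, and the 6 libraries were taken as separate samples from the labels.

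Genes with a mean of at least 10 normalized counts were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with empirical Bayes variances that follow a trend on the mean level. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called. A fold change is on the log2(value + 1) scale, which understates the change of genes with low counts, and is given as bbx14-1 minus wild type. The edgeR and DESeq2 packages were not used for any test here. The recovered reads were tested with limma's voom instead, as an alternative chosen after seeing the data.

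A set of 25 gene lists with 479 entries was fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Each list was tested again with its correlation estimated from the 6 libraries. In that mode camera uses the 4 residual degrees of freedom of the fit, so calls are hard to reach with 3 libraries per group. A call lost there can come from this alone and does not by itself show correlated members. The share of reads on plastid and mitochondrial genes was compared with an exact two-sided permutation test of 3 libraries against 3, which cannot give a p below 0.1. The named genes also followed a rule fixed before the data were examined. It took BBX14, then in each direction the 10 called genes with the largest fold change, a mean of at least 50 in the higher group and no overlap between the groups. It then took up to 4 called members per list with the smallest adjusted p, or the 2 most abundant where none was called. GLK1, GLK2, GUN1, HY5, BBX15, BBX16 and BBX17 were always included. Genes named outside the rule are marked as chosen after their values were seen.

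On simulated counts with the real means and library sizes, and 200 genes changed by a known fold among 18934 tested, the limma fit for bbx14-1 against wild type called 34.3% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 93.9% of those changed 4-fold. Of the 147 genes called, 5.44% were unchanged ones. Without the variance trend, 0%, 25.4% and 83.3% of the genes changed 1.5-fold, 2-fold and 4-fold were called. Of the 81 genes called without the trend, 11.1% were unchanged ones. The simulated dispersion depended on the mean level alone, so it carries no gene-specific spread.

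Gene symbols, biotypes and positions came from the annotation of TAIR10.1, to which 36632 of the 36917 identifiers could be matched. The 285 that could not be matched are plastid (133) and mitochondrial (152) identifiers, which are given as identifiers. Coordinates refer to TAIR10.1, whereas the submitters name TAIR10, and were used for the exon sequences, for overlaps between genes, and for the genes within 1 Mb of BBX14, QQS and AT3G29633. Of the 85 named genes, 19 overlap an annotated gene on the opposite strand, and 13 of those partners were tested with 0 called. A further 2 overlap a gene on the same strand, again with 0 partners called. Shared sequence was measured as the percent of 50-base windows of a gene's exons that occur elsewhere in the genome.

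Alternatives were other pseudocounts (0.5 and 5), no filter or a mean of at least 50, rescaling to upper quartiles or to equal nuclear totals, quantile normalization, variances without a trend, each library left out in turn, organelle genes left out, a fold threshold of 2, and the replicate number as a block. The voom test, the removal of a trend on exon length and GC content and, for the gene lists, leaving out organelle genes were added after seeing the data. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The series title also names GLK depletion, which was not analysed here.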

Results

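The data are normalized read counts of 6 ribosomal-RNA-depleted libraries from Arabidopsis seedlings on day 4, after 3 days in darkness and 1 day in light. The libraries form 2 groups of 3, wild type and bbx14-1, a line named for a lesion in the B-box transcription factor gene BBX14. Recovered depth was 20939505 to 32064650 reads per wild-type library and 25505859 to 32621183 per bbx14-1 library. Plastid-encoded genes took 49.61% to 56.67% of the reads of a library, which lowers the depth on nuclear genes. The series asks how the loss of BBX14 alters gene expression in dark-grown seedlings moved to light.

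BBX14 (AT1G68520) was measured first, as a check of the labels. In TAIR10.1 it lies on chromosome 1 from 25708175 to 25710989 on the minus strand, in 2 exon blocks. Its mRNA was not lower in the libraries labelled bbx14-1. The mean was 580 ± 90.0 normalized counts in wild type (SD, n = 3) and 767 ± 122 in the libraries labelled bbx14-1 (SD, n = 3), a log2 fold change of 0.40 with a standard error of 0.13. That difference did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.0726), although it did without wild type replicate 2 (0.53, limma adjusted p = 0.0199) and without bbx14-1 replicate 1 (0.52, limma adjusted p = 0.0306). The count covers all exons and does not tell an intact transcript from an altered one. Since the target gene gives no support to the label, the group is called the libraries labelled bbx14-1 throughout, and each direction below refers to that label.

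Between the groups, 883 of 19003 tested genes differed (limma, adjusted p under 0.05), 477 of them higher and 406 lower in the libraries labelled bbx14-1. Most changes were moderate, with 88 genes higher and 71 lower by at least 2-fold. Among genes with a clear level in both groups, the endoplasmic reticulum chaperone gene BIP3 rose from 20.6 ± 9.44 to 139 ± 28.8 normalized counts, a log2 fold change of 2.79 (limma, adjusted p = 9.43e-06). HB4, a homeodomain-leucine zipper gene, rose by 1.86 on the log2 scale from 52.7 ± 5.57 to 194 ± 20.04 (limma, adjusted p = 3.85e-06). At the other end, the cold-regulated gene COR27 fell by 2.73, from 276 ± 65.3 to 40.1 ± 4.93 (limma, adjusted p = 2.29e-08). AT5G05200 fell by 2.64, from 2076 ± 97.3 to 336 ± 53.6 (limma, adjusted p = 1.82e-13), and AT1G07050 fell by 3.15, from 132 ± 25.5 to 14.2 ± 4.49 (limma, adjusted p = 8.42e-07). All values are means ± SD with n = 3.

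A pair of genes on chromosome 3 was detected almost solely in the libraries labelled bbx14-1. QQS, a regulator of carbon and nitrogen allocation, had 1.91 ± 2.03 normalized counts in wild type and 307 ± 70.8 in the libraries labelled bbx14-1 (limma, adjusted p = 1.21e-09). AT3G29633 had 2.24 ± 3.88 and 368 ± 36.0 (limma, adjusted p = 4.77e-09). The wild-type levels are near the floor of 3 reads, so no fold is given. Among called genes with a mean of at least 50 normalized counts in the higher group and no overlap between the groups, the other genes of the 10 with the largest rise were AT5G35940 (log2 fold change 2.56), AT1G67105 (2.03), AT2G01010 (1.96), AT4G04223 (1.94), AT2G16586 (1.93) and AT1G18830 (1.86). Under the same limits, those with the largest fall included AT2G43620, AT4G33980, AT1G22490 and VIM1, at log2 fold changes of -2.55, -1.92, -1.86 and -1.74. The call of AT2G43620 was lost without wild type replicate 1 (-1.81, limma adjusted p = 0.128), where that library held 207 normalized counts against 62.8 and 30.3 in the other wild-type libraries. The call of VIM1 was lost without wild type replicate 2 (-1.37, limma adjusted p = 0.0557).

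**Figure D1:**
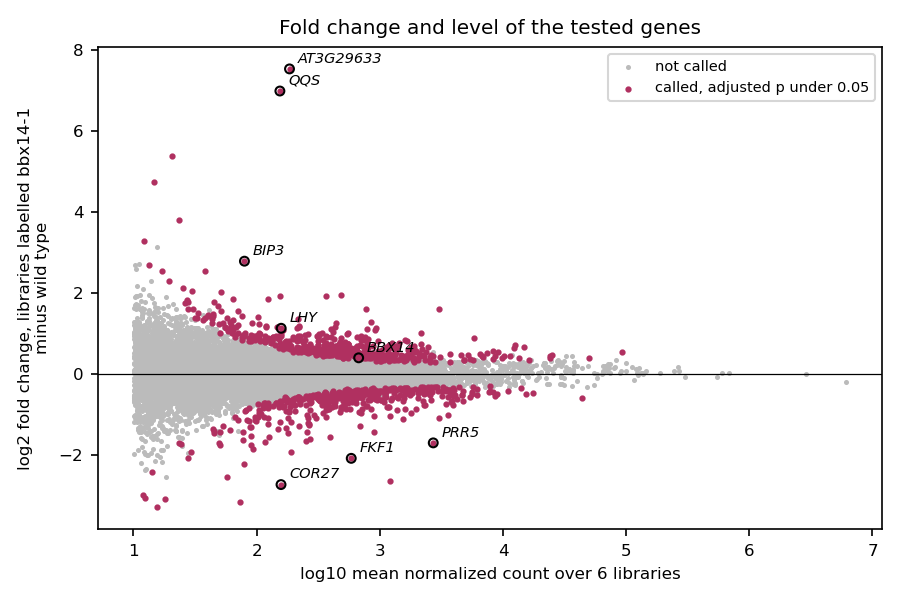
Log2 fold change (libraries labelled bbx14-1 minus wild type) against the log10 mean normalized count of the 19003 tested genes; each point is a gene, coloured where it was called by limma. QQS and AT3G29633 lie far above the rest, FKF1, PRR5 and COR27 are among the largest falls, and BBX14 lies above 0 at 0.40 without being called.

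The 883 calls rest on the shared variance trend. Without the trend limma called 28 genes, 13 higher and 15 lower, and 14 of the 68 named calls were kept, among them FKF1, PRR5, TOC1, BBX8, COR27, HB4, QQS and IRT1. The count was 529 without wild type replicate 1 and 577 without wild type replicate 3, and higher calls numbered 290 without bbx14-1 replicate 2.

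Most genes of the circadian clock had a negative fold change, 15 of 20 tested. Of the 20 members, 8 were called lower and 2 higher (13 lower and 4 higher when adjusted over the list alone), with a median log2 fold change of -0.33. FKF1, a blue-light receptor of the photoperiod pathway, fell by 2.08, from 950 ± 48.7 to 224 ± 9.41 normalized counts (limma, adjusted p = 2.28e-11). The pseudo-response regulator gene PRR5 fell by 1.70, from 4153 ± 461 to 1282 ± 187, and its relative TOC1 fell by 1.098, from 2103 ± 96.7 to 982 ± 52.3 (limma, adjusted p = 1.87e-10 and 3.60e-08). RVE1, a MYB-like gene linked to auxin, fell by 0.87 (limma, adjusted p = 1.70e-05). The 2 called members that rose, named after their values were seen, were the morning gene LHY (log2 fold change 1.13) and CHE (0.41). The list was called lower by camera (adjusted p = 4.35e-06) and the call was lost with an estimated correlation (adjusted p = 0.128). That estimate was -0.023, below the preset 0.01, so a higher correlation did not end the call. The loss came from the 4 degrees of freedom of that mode, where the unadjusted camera p was 0.00512, against 3.48e-07 with the preset.

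**Figure D2:**
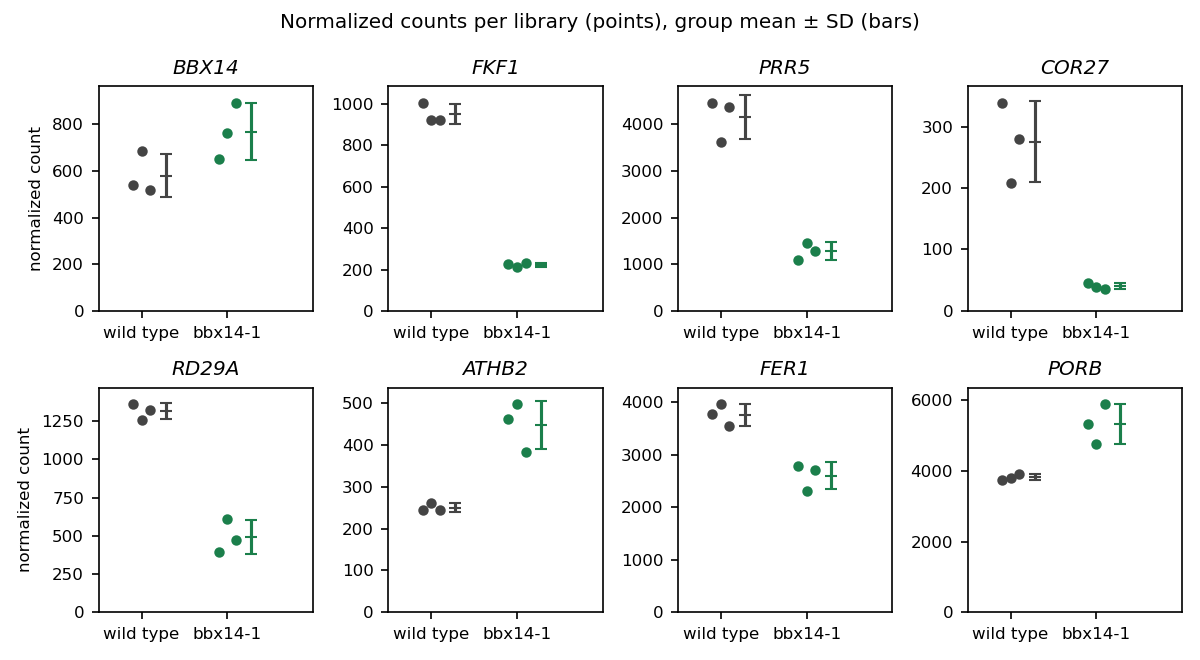
Normalized counts of 8 genes in each library; points are the 3 libraries of each group, and the bar beside them gives the mean ± SD, on axes that start at 0. BBX14 was not lower in the libraries labelled bbx14-1 (767 against 580), whereas FKF1, PRR5, COR27, RD29A and FER1 were lower and ATHB2 and PORB higher in all 3 of them.

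The B-box family to which BBX14 belongs had changes in both directions. Of 26 tested members without BBX14, 2 were called higher and 2 lower (2 and 5 when adjusted over the list alone). BBX8 fell by 1.60, from 405 ± 30.8 to 134 ± 25.4 normalized counts, and BBX7 fell by 1.27, from 380 ± 55.2 to 156 ± 15.6 (limma, adjusted p = 5.27e-07 and 9.60e-06). BBX27 rose by 0.57, from 515 ± 9.82 to 766 ± 33.1 (limma, adjusted p = 0.00146). BBX16, of the same subgroup as BBX14, rose by 0.83, from 82.2 ± 12.0 to 152 ± 49.6 (limma, adjusted p = 0.0467), a call lost in 7 settings that kept the variance trend, with values from 0.67 to 1.13 over all alternatives. BBX15 and BBX17 were at -0.11 and -0.04, neither called. The family list was called lower by camera (adjusted p = 0.041), a call lost with an estimated correlation (adjusted p = 0.376) and without wild type replicate 2, wild type replicate 3 or bbx14-1 replicate 1 (adjusted p = 0.0724, 0.161 and 0.157).

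Most abscisic acid and cold response genes had a negative fold change, 14 of 15 tested. Of the 15 members, 8 were called lower and 0 higher (10 and 0 when adjusted over the list alone), with a median log2 fold change of -0.82. RD29A, a gene induced by dehydration and cold, fell by 1.43, from 1314 ± 51.3 to 493 ± 111 normalized counts (limma, adjusted p = 7.65e-08). The dehydrin gene RAB18 fell by 1.75, KIN2 by 1.08 and RD29B by 0.82 (limma, adjusted p = 0.000221, 0.000187 and 0.00078). The list was called by camera (adjusted p = 3.16e-08) but not with an estimated correlation (adjusted p = 0.172). In the seed storage and lipid reserve list, 2 of 8 tested members were called lower and 0 higher (5 and 0 when adjusted over the list alone). The glyoxylate cycle gene ICL fell by 0.85, from 2064 ± 307 to 1152 ± 242, and the seed storage protein gene CRC fell by 2.22 (limma, adjusted p = 9.16e-05 and 0.00146). Wild type replicate 1 held 276 normalized counts of CRC against 70.3 and 58.5 in the other wild-type libraries, and all 3 exceeded the 19.3 to 24.0 of the libraries labelled bbx14-1. The seed list was called lower by camera (adjusted p = 9.03e-05), though not with an estimated correlation (adjusted p = 0.362).

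Some auxin response and hypocotyl elongation genes were higher. Of 27 tested members, 8 were called higher and 0 lower (9 and 0 when adjusted over the list alone), and 4 had a negative fold change. The shade-responsive homeobox gene ATHB2 rose by 0.83, from 249 ± 10.2 to 447 ± 57.9 normalized counts (limma, adjusted p = 0.000352). The auxin repressor gene IAA3 rose by 0.60, the cell-wall enzyme gene XTH15 by 0.72 and the auxin biosynthesis gene TAA1 by 0.76 (limma, adjusted p = 0.00224, 0.00524 and 0.0101). TAA1 lost its call without bbx14-1 replicate 1 (0.70, limma adjusted p = 0.0576). The list was called higher by camera (adjusted p = 9.03e-05), though not with an estimated correlation (adjusted p = 0.252). Cell cycle genes, all 11 with a positive fold change and 0 called (1 higher when adjusted over the list alone), were called higher as a list (camera, adjusted p = 0.00143), but not with an estimated correlation (adjusted p = 0.172). Their most abundant members TSO2 and CDKB2;1 were at 0.19 and 0.06. The correlation estimated for the cell cycle list was -0.054, also below the preset 0.01, so that loss too came from the 4 degrees of freedom.

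Several photosynthesis genes of the nucleus were modestly higher. In tetrapyrrole biosynthesis, the chlorophyll pathway, 4 of 30 tested members were called higher and 0 lower (10 higher and 1 lower when adjusted over the list alone). The protochlorophyllide oxidoreductase genes PORB and PORC rose by 0.48 and 0.51, PORB from 3816 ± 82.6 to 5324 ± 557 normalized counts (limma, adjusted p = 0.00176 and 0.00345). PORA rose by 1.61 from a low level, 14.5 ± 2.92 to 46.1 ± 8.56, and CAO by 0.36 (limma, adjusted p = 0.0156 and 0.0237). PORA lost its call without wild type replicate 1 (1.48, limma adjusted p = 0.0579) or bbx14-1 replicate 3 (1.46, limma adjusted p = 0.0936). CAO lost it without wild type replicate 1, wild type replicate 2 or bbx14-1 replicate 2 (limma, adjusted p = 0.0807, 0.128 and 0.145). Among 36 nuclear photosystem and electron transport genes, 5 were called higher and 0 lower (11 higher and 2 lower when adjusted over the list alone). The plastocyanin gene PETE1 rose by 0.54, ATPD by 0.52, PSAH2 by 0.46 and PSAG by 0.47 (limma, adjusted p = 0.000471, 0.00169, 0.00225 and 0.00642). PSAG lost its call without wild type replicate 1 or bbx14-1 replicate 2 (limma, adjusted p = 0.0705 and 0.0519).

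Of 20 light-harvesting complex genes, 2 were called higher and 0 lower (5 and 0 when adjusted over the list alone). LHCB2.4 rose by 0.67, from 11449 ± 238 to 18295 ± 1536 normalized counts (limma, adjusted p = 4.93e-05). LHCB2.2 rose by 0.40 (limma, adjusted p = 0.0342), with 29.5% of its 50-base windows found elsewhere in the genome, and lost its call in 5 of the 6 settings that leave out a library (limma, adjusted p from 0.0513 to 0.169), with no filter (limma, adjusted p = 0.0992) and with the replicate number as a block (limma, adjusted p = 0.0578). By camera, the tetrapyrrole (adjusted p = 0.00513), photosystem (0.000422) and light-harvesting lists (0.0247) were called higher. With an estimated correlation none was (adjusted p = 0.469, 0.621 and 0.666), and the light-harvesting call was also lost under quantile normalization (adjusted p = 0.416), with the replicate number as a block (adjusted p = 0.0553), without wild type replicate 1 (adjusted p = 0.0628) and without bbx14-1 replicate 3 (adjusted p = 0.328). In the Calvin-Benson cycle 1 of 19 members was called, RBCS2B, which rose by 0.39 (limma, adjusted p = 0.0203; 0.125 under quantile normalization and 0.0507 to 0.126 without wild type replicates 1, 2 or 3 or bbx14-1 replicate 3), with 16.9% of its windows found elsewhere, and 2 members were higher and 2 lower when adjusted over the list alone. That list was not called (camera, adjusted p = 0.798), nor was photorespiration (camera, adjusted p = 0.133), where GGT1 and AGT1 were at -0.16 and -0.25 and 0 of 13 members were called (0 when adjusted over the list alone). Under quantile normalization the photorespiration list was called lower (camera, adjusted p = 0.0247), as was AGT1 (limma, adjusted p = 0.00309).

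Among regulators of chloroplast development and protein import, 1 of 14 tested members was called lower and 0 higher (the same counts when adjusted over the list alone; camera, adjusted p = 0.055). The list was called lower with no filter, with voom and without wild type replicate 2 or bbx14-1 replicate 3 (camera, adjusted p = 0.0342, 0.0149, 0.0225 and 0.0161). The called member was the GATA factor gene GNC, which fell by 0.42 (limma, adjusted p = 0.0355), a call lost under quantile normalization and without wild type replicates 1 or 3 or bbx14-1 replicates 2 or 3 (limma, adjusted p from 0.056 to 0.228). GLK1 and GLK2, activators of photosynthesis genes, were at 764 ± 150 and 1008 ± 191 normalized counts in wild type and at 710 ± 31.8 and 1159 ± 216 in the libraries labelled bbx14-1, and neither was called (limma, adjusted p = 0.801 and 0.465). GUN1, of plastid-to-nucleus signalling, and HY5, of light signalling, were not called either, at log2 fold changes of -0.19 and -0.51 (limma, adjusted p = 0.274 and 0.397). In the light signalling list PIF4 was the 1 member called of 19 (1 when adjusted over the list alone; camera, adjusted p = 0.387). It rose by 0.41 (limma, adjusted p = 0.0192), a call lost without wild type replicate 1 or bbx14-1 replicates 2 or 3 (limma, adjusted p = 0.158, 0.0793 and 0.0683). Of 19 genes of the plastid transcription machinery 1 was called, FLN1, which fell by 0.68 (limma, adjusted p = 0.0256; 0.0616 to 0.14 without wild type replicates 1 or 2 or bbx14-1 replicates 2 or 3), and 2 were lower when adjusted over the list alone (camera, adjusted p = 0.195).

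Plastid-encoded genes took 54.6% ± 1.71 of the reads in wild type and 53.6% ± 3.62 in the libraries labelled bbx14-1 (SD, n = 3), a difference within the spread (exact two-sided permutation p = 0.8). Mitochondrion-encoded genes took 0.450% ± 0.0326 and 0.470% ± 0.0258 (exact two-sided permutation p = 0.5, n = 3). The 3-against-3 design cannot give a p below 0.1. The plastid difference changed sign without bbx14-1 replicate 3 (from -0.98 to 1.02 percentage points) and when the 10 most abundant genes were left out of the total (1.39). Within the plastid genome, 16 of 118 tested genes were called higher and 0 lower, against 1 higher and 1 lower of 71 mitochondrial genes. In the expression and housekeeping list, 6 of 17 members were called higher (10 when adjusted over the list alone; camera, adjusted p = 7.83e-05; adjusted p = 0.482 with an estimated correlation), led by ATCG01130, which rose by 0.65 (limma, adjusted p = 0.00103). Its called member ATCG00190 lost the call without wild type replicate 1 or bbx14-1 replicate 2 (limma, adjusted p = 0.0831 and 0.0694). ATCG00050 lost it without wild type replicates 1 or 2 or bbx14-1 replicates 1 or 2 (limma, adjusted p from 0.0544 to 0.206). Of 30 plastid-encoded photosynthesis genes 3 were called higher (5 when adjusted over the list alone), led by ATCG00590 at 1.02 (limma, adjusted p = 0.0033). The other called members, ATCG00690 and ATCG00600, lost their calls under quantile normalization (limma, adjusted p = 0.121 and 0.0815). They also lost them without wild type replicates 2 or 3 or bbx14-1 replicate 2 (limma, adjusted p from 0.0623 to 0.225). For ATCG00590 and ATCG00600, wild type replicate 1 (2230 and 10196 normalized counts) exceeded bbx14-1 replicate 1 (2001 and 10133). Of 12 ndh genes 0 were called (0 when adjusted over the list alone). Neither of those lists was called (camera, adjusted p = 0.0597 for both), but both were at a mean of at least 50 (0.0442 and 0.0471), with voom (0.00369 and 0.00521) and without bbx14-1 replicate 3 (0.00261 and 0.0161), and the photosynthesis list also without wild type replicate 1 (0.0498, each an adjusted p from camera). The libraries labelled bbx14-1 also held more of the residual ribosomal RNA gene AT2G01010, at 447, 559 and 1324 normalized counts against 159, 285 and 123 in wild type.

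Iron homeostasis genes moved in both directions, with 3 of 11 tested members called higher and 2 lower (3 and 3 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.237). The ferritin genes FER1 and FER4, which store iron, fell by 0.54 and 0.63, FER1 from 3760 ± 211 to 2598 ± 255 normalized counts (limma, adjusted p = 0.000608 and 0.00306). The iron transporter gene IRT1 had 0 reads in all 3 wild-type libraries and 29.2 ± 16.6 normalized counts in the libraries labelled bbx14-1 (limma, adjusted p = 0.00199). That mean is 9.39-fold above a floor of 3 reads per library, but the libraries varied, at 30.4, 45.1 and 12.0 normalized counts. OPT3 rose by 0.40 (limma, adjusted p = 0.0283), a call lost without wild type replicates 1 or 3 or bbx14-1 replicates 2 or 3 (limma, adjusted p = 0.165, 0.0667, 0.0892 and 0.13). NAS4, named after its values were seen, completed the 3 that rose.

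In the sugar starvation and dark-inducible list, 2 of 14 members were called lower and 0 higher (4 and 0 when adjusted over the list alone). DIN2 fell by 0.86, from 2547 ± 67.2 to 1411 ± 223 normalized counts, and BCAT2 by 0.77 (limma, adjusted p = 7.58e-06 and 3.45e-05). The list was called lower by camera (adjusted p = 0.041), a call lost with an estimated correlation (adjusted p = 0.666), under quantile normalization (adjusted p = 0.0726), with the replicate number as a block (adjusted p = 0.0552), and without wild type replicate 2 or bbx14-1 replicate 2 (adjusted p = 0.249 and 0.457). The anthocyanin repressor gene MYBL2 fell by 0.73, from 4284 ± 168 to 2588 ± 141, the 1 called of 14 flavonoid genes (1 higher and 1 lower when adjusted over the list alone), and the violaxanthin de-epoxidase gene VDE fell by 0.64, the 1 called of 15 carotenoid genes (0 higher and 1 lower when adjusted over the list alone; limma, adjusted p = 6.03e-06 and 0.000438). In the oxidative and heat stress list 2 of 11 were called (2 lower when adjusted over the list alone). BCB fell by 1.08 and CSD2 by 0.36 (limma, adjusted p = 9.10e-07 and 0.0262), with the CSD2 call lost without wild type replicates 2 or 3 or bbx14-1 replicates 1 or 2 (limma, adjusted p from 0.0548 to 0.158). In the defence and jasmonate list the 2 called of 13 were higher (2 higher and 1 lower when adjusted over the list alone). VSP2 rose by 1.52 and AOS by 0.50 (limma, adjusted p = 0.0144 and 0.00919). VSP2 lost its call without bbx14-1 replicate 2 (limma, adjusted p = 0.102), and AOS without that library or wild type replicate 3 (limma, adjusted p = 0.0625 and 0.0512). None of these last 4 lists was called (camera, adjusted p = 0.984 for flavonoid, 0.581 for carotenoid, 0.523 for stress and 0.274 for defence genes). The defence list had a median of 0.07 and a mean of -0.00041.

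Of 9 root markers and 12 reference genes 0 were called in either list (2 higher and 0 when adjusted over the list alone; camera, adjusted p = 0.365 and 0.48). The root genes PHO1 and SCR were at 0.29 and 0.14, and the reference genes UBQ10 and ACT2 at -0.25 and -0.23. Both reference genes were called lower under quantile normalization (limma, adjusted p = 0.00322 and 0.00527), and UBQ10 also without bbx14-1 replicate 3 (limma, adjusted p = 0.0373). In all, 11 of 25 lists were called with the preset correlation, 6 higher and 5 lower, and 0 with an estimated correlation. The latter mode has 4 degrees of freedom, so the loss of all calls does not show that correlation between members ended them.

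**Figure D3:**
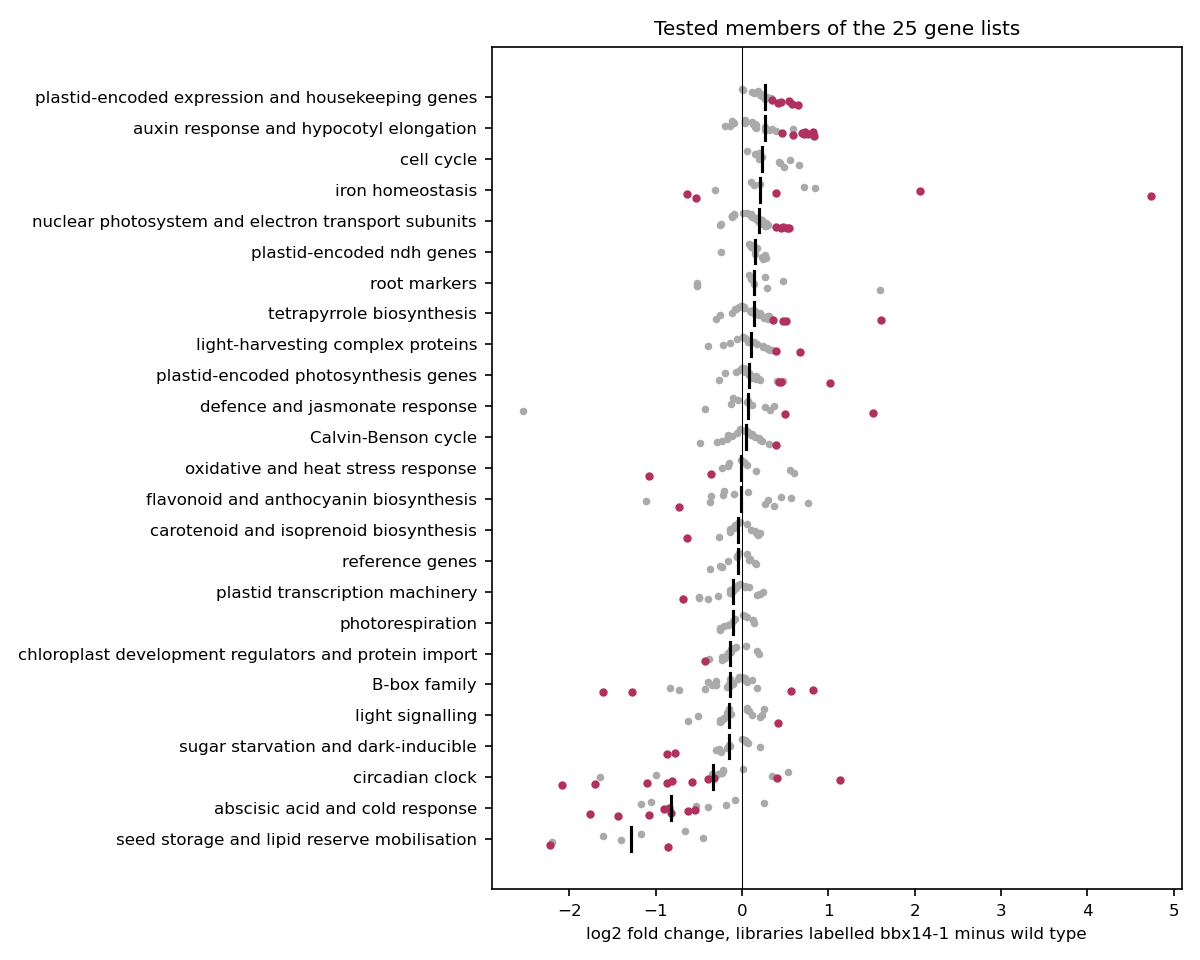
Log2 fold change (libraries labelled bbx14-1 minus wild type) of every tested member of the 25 gene lists; each point is a gene, coloured where it was called by limma, and the black bar is the list's median. The seed storage (-1.29), abscisic acid and cold (-0.82) and clock (-0.33) lists have the lowest medians.

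Among nuclear non-coding genes, 9 of 368 tested were called higher and 5 lower. The called share was 3.8%, against 4.61% of 18332 protein-coding genes (Fisher's exact test, two-sided p = 0.531). AT4G04223 rose from 63.4 ± 4.89 to 247 ± 26.8 normalized counts and AT1G67105 from 19.8 ± 5.51 to 83.9 ± 20.3 (limma, adjusted p = 3.99e-07 and 0.000474). For AT4G04223, AT2G16586 and the ribosomal gene AT2G01010, 71.5%, 39.3% and 94.3% of the 50-base windows occur elsewhere in the genome, so their counts are uncertain.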

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

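The voom test, the length and GC correction and, for the lists, leaving out organelle genes were chosen after seeing the data; the other alternatives were fixed before. The count of 883 called genes stayed between 828 and 926 under the block, pseudocount, filter, scaling, organelle and voom alternatives (898 with voom, 853 of them shared). It fell to 28 (13 higher, 15 lower) without a variance trend, where the prior degrees of freedom dropped from 19.7 to 2.34 beside 4 residual ones, and requiring 2-fold changes left 159 (88 higher, 71 lower). Without 1 library it ranged from 529 to 762, with 282 to 437 higher (290 without bbx14-1 replicate 2) and 247 to 406 lower calls. BBX14 stayed above 0, at 0.29 to 0.53 without 1 library. Of 68 named calls, 20 were lost in at least 1 setting that kept the trend, and 0 were reversed. Of 11 list calls, 8 held in every setting they were tested in except the estimated correlation, which left 0 on 4 degrees of freedom. The plastid-encoded list among them was not tested without organelle genes or after the length and GC correction, and the setting without a variance trend does not apply to camera, which was run without one. Outside the calls, the direction changed for the Calvin-Benson mean (-0.026 with quantile normalization; -0.042 to 0.097 without 1 library), light signalling (-0.12 to 0.0029), flavonoid genes (mean -0.020 as reported, 0.16 with no filter and 0.040 at a mean of at least 50; -0.063 to 0.095 without 1 library; the mean stayed negative, at -0.019, after the length and GC correction, where only camera's direction against the other genes changed), stress genes (-0.12 to 0.044), iron genes (-0.088 at a mean of at least 50), GLK1 (-0.25 to 0.034) and BBX17 (0.025 with voom; -0.26 to 0.17). The plastid share difference was -2.50 to 1.02 percentage points without 1 library and 1.39 without the 10 most abundant genes. Causes were not tested, and a fit that leaves out a library also has fewer samples. The planned edgeR and DESeq2 tests were not run.

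With the replicate number as a block 915 genes were called, 842 of them shared. Deviations of same-numbered libraries correlated at 0.0425, 0.0175 and -0.0302, so no pairing by number was visible in the values. These correlations cannot tell whether same-numbered samples were grown or handled together. Among lists, the block ended the light-harvesting (adjusted p = 0.0553) and sugar starvation (adjusted p = 0.0552) calls, and among named genes that of LHCB2.2 (limma, adjusted p = 0.0578). The plastid share difference was unchanged at -0.98 by construction.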

Other observations

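A scan of 111 families of genes sharing a symbol prefix, chosen after the data were seen, called 7 by camera, 5 higher and 2 lower. Of 20 tested arabinogalactan protein (AGP) genes 6 were called higher and 0 lower, with a median log2 fold change of 0.55. AGP16 rose by 0.81, from 1208 ± 139 to 2120 ± 285 normalized counts, and AGP15 by 0.52 (limma, adjusted p = 2.82e-05 and 0.000599). Of 13 fasciclin-like arabinogalactan (FLA) genes 6 were called higher and 0 lower, led by FLA9 at 0.66 (limma, adjusted p = 0.000101). Of 22 xyloglucan endotransglucosylase (XTH) genes 6 were called higher and 0 lower, with XTH9 up by 1.26 from 262 ± 14.2 to 628 ± 46.6 and XTH16 by 1.13 (limma, adjusted p = 3.25e-07 and 9.41e-07). These AGP, FLA and XTH families had the smallest adjusted p (camera, adjusted p = 4.61e-06, 0.000477 and 0.0023). With an estimated correlation 0 of 111 families were called (camera, adjusted p = 0.435 for AGP, 0.646 for XTH and 0.815 for the other 5). That mode has 4 degrees of freedom and little power over 111 families, so it does not tell whether correlated members explain the calls. In the other 4 families called by camera, fewer members were called by limma, while camera weighs all members of a family. KCS was called higher (adjusted p = 0.0292) with 3 of 15 members called higher and 1 lower, and that 1, KCS12, had the smallest adjusted p of the family and fell by 0.79 (limma, adjusted p = 9.76e-05). SAUR was called higher (adjusted p = 0.0329) with 1 of 15 members called, and ECT and UGT were called lower (adjusted p = 0.0292 and 0.0312) with 2 of 11 and 2 of 40 called. The expansin family EXPA, which also acts on the cell wall, was not called (median -0.10; camera, adjusted p = 0.832), with 2 of 15 members called higher and 1 lower.

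The tests of exchanged labels, of the clock phase and of the chromosome segment were chosen after the results were seen. The first pattern is that BBX14 mRNA was not lower in the libraries labelled bbx14-1. Reads from a copy elsewhere in the genome are argued against, since 0% of the 50-base windows of the BBX14 exons occur elsewhere. Reads of AT1G68510, which overlaps BBX14 on the opposite strand, stay open. The windows do not cover a gene at the same position, and the strand setting of the counting is not given. An exchange of a wild-type and a bbx14-1 library is argued against as well, because all 6 libraries correlated better with their own group than with the other. An exchange of the groups as a whole stays open: the ratio of BBX14 in wild type to the other group was 0.757, neither the deep loss nor the excess that would have decided it. An allele that alters the protein but leaves the transcript countable may also apply, and was not tested, since the nature of the allele is not given in the sources used here.

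The second pattern is the change of clock genes. Reads from copies elsewhere in the genome are argued against, since the median share of 50-base windows of the 10 called clock genes that occur elsewhere was 0%. The windows do not cover genes on the opposite strand at the same position, such as those that overlap FKF1 and RVE1. A harvest or light shift at an earlier clock phase in the libraries labelled bbx14-1 may contribute but stays open: with classes set after the values were seen, the 8 evening-phased genes had a median log2 fold change of -1.05 with 0 above 0, the 7 dawn-phased genes a median of 0.02 with 4 above 0, and the classes differed (exact two-sided permutation p = 0.00218). With RVE4 and RVE6 added, the 9 dawn-phased genes had a median of -0.22 with 4 above 0, so the rise that an earlier phase predicts was not met although the classes still differed (exact two-sided permutation p = 0.00074). Genes of 1 clock are not independent, and RVE1, counted as dawn-phased, fell by 0.87. CHE, PRR7 and ZTL of the clock list were placed in neither class, at log2 fold changes of 0.41, -0.32 and -0.22. The medians and p-values of the classes depend on these choices. A direct effect of the genotype was not tested, and nothing here separates it from harvest time. Genes outside the clock list, such as COR27 and the abscisic acid and cold genes, were placed in no phase class. Whether harvest time changed them was not tested either.

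The third pattern is the detection of QQS and AT3G29633 almost solely in the libraries labelled bbx14-1. Reads of other loci are argued against, since 0% of the 50-base windows of either gene occur elsewhere. A chromosome segment that differs between the lines may account for it: of 96 other tested genes within 1 Mb of either gene, 4 were called at 2-fold or more (4.17%, against 0.812% of 18716 genes elsewhere; permutation p = 0.0183 from 18812 rotations of the calls along the genome). Those 4 were AT3G28550, P1R3 and AT3G29644, which were higher, and AT3G05955, which was lower. AT3G28550 passed narrowly, at a log2 fold change of 1.0017. AT3G29644 and AT3G05955 are non-coding genes of low level, at 22.1 and 22.4 normalized counts in wild type. The rotations did not match genes for level or biotype, so their p does not separate a differing segment from the kinds of genes that lie there. A heritable difference in expression state without a sequence difference was not tested.

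The real grouping called 883 genes and the highest of the other 9 splits of the 6 libraries called 2, so 1 of 10 splits gave as many. With 10 splits the share cannot fall under 0.05. Each other split mixes libraries of both groups, so a difference between the groups adds to the spread within each side. Their low counts therefore do not give the number of calls that arise by chance.

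In TAIR10.1, FKF1, the clock gene with the largest fall, starts at 25508639 on chromosome 1, 199.5 kb from the start of BBX14, and the called B-box gene BBX27 lies between them, 149.4 kb from BBX14. Of 335 other tested genes within 1 Mb of BBX14, 23 were called by limma (6.87%), 5 of them at 2-fold or more. Of all 19003 tested genes, 4.65% were called, and 159 genes were called at 2-fold or more. Those at 2-fold or more within 1 Mb of BBX14 include FKF1, which fell, and AT1G67105, which rose and starts at 25057479. Whether a sequence difference linked to BBX14, and not a change of BBX14 itself, changed FKF1 and BBX27 was not tested.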
